A study of Homo sapiens with 5 samples.

How the data were processed

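Total RNA of HCT116 colorectal carcinoma cells carrying an empty, a TRA2B4 or a TRA2B exon 2 expression vector was labelled with Cy3 and hybridised to single-colour Agilent whole human genome arrays, per the labels' protocols. The series text and the extraction protocol name different RNA reagents, so the reagent is not given here. There were 5 arrays (mock 1, TRA2B4 2, exon 2 2), grouped and numbered by their titles.

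The spot intensity in each scanner file was extracted with Agilent Feature Extraction 11.5.1.1, per the file headers, and the processed intensity used here had been background-subtracted and spatially detrended within the array by that program, with no scaling between arrays. The scanner files also hold the median spot and local background intensity and flags for spots well above background, saturated or outlying, per the file headers. The table of the whole series holds log2 values deposited by the authors; its scale was found from the values, since differences between its columns and those of the log2 processed intensity less the array's 75th percentile correlated at 0.999996 or more over 19799 matched probes. A baseline per probe had been subtracted in it that was not the median of these 5 columns and is not given in the sources used here. All its matched probes were well above background on all 5 arrays. As an alternative, the table therefore nearly repeats the setting with only such probes. Its column medians were 0.04 (mock), -0.01 and -0.03 (TRA2B4 1 and 2) and 0.00 (both exon 2 arrays), and direction between columns was that of the scanner values. The software behind that table is not given in the sources used here, beyond Feature Extraction per the submitters' processing notes.

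Control spots were left out, spots of a probe were averaged, and 40 of 50599 probes flagged as outliers on an array were left out. Values were log2 of the processed intensity less each array's 75th percentile. Probes were named by their RefSeq accession through a reference table of the current human assembly, which matched 29979 of 50559 probes; 20580 kept the name in the file. The arrays' grid and that table are on different builds, so no coordinates are given. A probe entered the tests if it was well above background on every array of at least 1 group (22527 probes), and the brightest probe stood for a gene (17861 features, 3617 of them with several probes).

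The comparisons were TRA2B4 against mock, exon 2 against mock and exon 2 against TRA2B4, in 1 limma fit (lmFit and eBayes, version 3.58.1, in R 4.3.3) over all 5 arrays, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom, which came from the replicated groups, and 3.75 after the empirical Bayes step. The number of arrays limits the precision: the typical 95% interval of a log2 fold change reached 0.36 to either side against mock and 0.29 between the constructs. Where a gene was not well above background on any array of a group, its fold is given as at least the bright group's mean over the dim group's mean of, per array, the higher of the lowest well-above-background signal and the probe's own.

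The design, the 26 gene lists, the cell type markers, the rule for named genes and all but 1 of the alternatives were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, beside camera with an estimated correlation and fry. With an estimated correlation camera works with the fit's 2 residual degrees of freedom, so a list could hardly pass. A call lost in that setting need not be due to correlation. Named genes were TRA2B by probe, the 10 called genes with a symbol with the largest rise and the 10 with the largest fall whose arrays did not overlap and whose brighter group was well above background on every array (filled by the largest fold where too few passed; folds were ranked by signal, also where it was at background), and from each list up to 4 members with the smallest p. No test was named in the labels.

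The 5 arrays lay on 1 slide with 1 scan time, so neither could be a batch; TRA2B4 1 and exon 2 1 lay in 1 row of the slide and the other 3 arrays in the other, and each group lay in its own slide column, so slide column cannot be separated from group. Alternatives were other scalings and background corrections (normexp with an offset of 50 on the median intensity, since the files hold no mean), other filters, other uses of several probes, another variance model, fewer arrays, the authors' table, a fold minimum of 2, leaving out each array, the replicate number as a block, and, added after seeing the data, the slide row as a covariate. No group held 3 samples, so other splits of the samples were not counted. The scripts were tested on simulated data with the fitted variances and 200 of 17861 genes changed (20 datasets each). For TRA2B4 against mock, 1.87% of genes changed by 1 (log2), 64.2% by 2 and 82.2% by 3 were recovered, with 5.35 false calls of 104 on average. For exon 2 against mock these were 1.87%, 63.4% and 83.1%, with 5.50 of 104, and for exon 2 against TRA2B4 22.8%, 74.9% and 89.4%, with 5.85 of 130. In the data, limma gave 5911 (TRA2B4) and 6141 (exon 2) features an unadjusted p under 0.05 against mock, far more than 200. Recovery depends on that share, and the simulated mock varied like the other groups. The rates therefore check the scripts and do not describe the comparisons with mock.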

Results

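HCT116, a human colorectal carcinoma cell line, had been stably transfected with an empty vector (mock), a vector for full-length TRA2B4, or a vector for exon 2 of TRA2B alone. TRA2B encodes a splicing factor related to the serine- and arginine-rich (SR) proteins, and its exon 2 holds an ultraconserved region. Full-length TRA2B4 includes exon 2, so both constructs carry that region. The series asked how expression of that region affects colon cancer cells. RNA was measured on 5 single-colour Agilent arrays, of which 1 was mock, 2 were TRA2B4 and 2 were exon 2. Between 42.9% and 45.8% of the 50559 probes were well above background on each array, and no spot was saturated. A total of 17861 genes and transcripts were tested, of which 13666 carried a gene symbol. Over these, the log2 difference between the mock array and each of the others had an SD of 0.68 to 0.73, against 0.43 to 0.47 between TRA2B4 replicate 2 and the other overexpressing arrays and 0.29 to 0.35 among those 3. Features well above background on the mock array alone were tested, but none so on 1 overexpressing array alone. That raises the range for mock, so these ranges are not like for like. With 1 mock array, every standard error against mock assumed that the mock culture varies as much as the replicated groups. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

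TRA2B itself was read first, since it is the gene both constructs derive from. The array carried a pair of TRA2B probes. Probe A_33_P3297517 was 2.14 ± 0.22 (SE, log2; 4.40-fold) higher in TRA2B4 (5.40 ± 0.25, SD, n = 2) than in mock (3.26, n = 1), with an adjusted p of 0.0521 over all probes in limma. It passed with quantile scaling (adjusted p = 0.0474), median scaling (0.0426), both normexp settings (0.00839 and 0.00989), a trended and robust variance model (0.0126) and the authors' values (0.0448), and missed the threshold with any 1 overexpressing array left out (0.0857 to 0.147) and with the slide row as a covariate (2.11, adjusted p = 0.130). In the exon 2 arrays the same probe lay at 3.49 ± 0.19 (SD, n = 2), which was 0.23 ± 0.22 above mock, adjusted p = 0.494. Probe A_23_P212639 was 0.37 ± 0.09 higher in TRA2B4 than in mock, adjusted p = 0.0977, and 0.13 ± 0.09 higher in exon 2, adjusted p = 0.389. The positions of the probes within TRA2B are not given in the sources used here, so these values do not check the exon 2 construct.

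**Figure D1:**
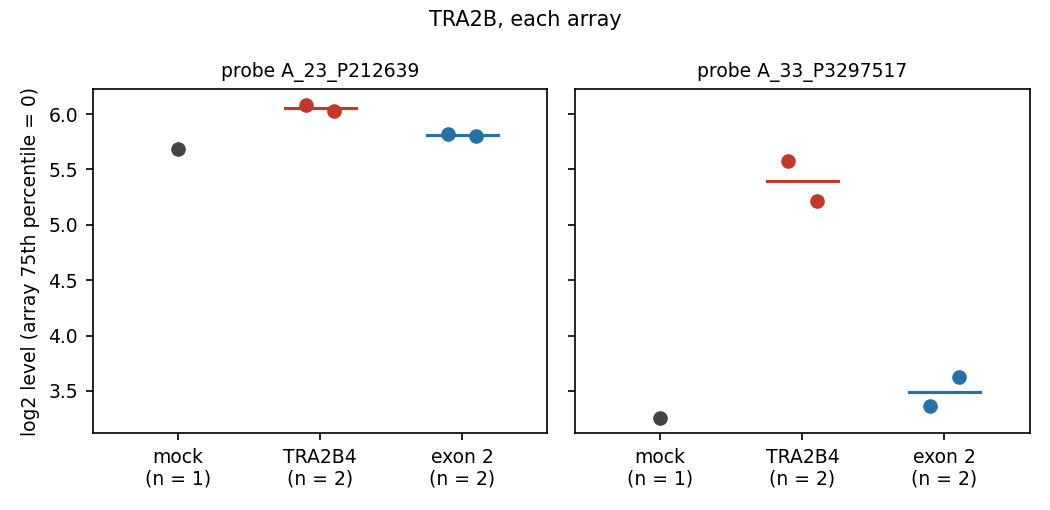
Log2 level of the 2 TRA2B probes (vertical axis, 0 at the array's 75th percentile) in mock, TRA2B4 and exon 2 cells (horizontal axis), with points for single arrays and lines for the means of groups with n = 2. For A_33_P3297517 the TRA2B4 arrays lay at 5.22 and 5.58, above the other arrays, which lay between 3.26 and 3.62.

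The comparison of TRA2B4 with mock asked what the full-length transcript changes. Of 33 measured genes of the amino acid and endoplasmic reticulum (ER) stress response, 14 fell in TRA2B4 cells, 1 rose and 18 did not pass, and the list's call had an adjusted p of 0.494 with an estimated correlation. CHAC1, which encodes a glutathione-degrading enzyme, fell by 3.69 ± 0.10 (SE, log2; 12.9-fold; TRA2B4 n = 2, mock n = 1), and ASNS, asparagine synthetase, fell by 1.69 ± 0.09. The immediate early transcription factor genes EGR1 and JUN fell 3.30-fold and 3.88-fold. Among genes that rose were SEL1L, an adaptor of ER-associated protein degradation, at 6.12-fold, TIPARP, a mono-ADP-ribosyltransferase, at 2.99-fold, H19, an imprinted long noncoding RNA, at 2.91-fold, and CDK6, a kinase of the G1 phase, at 2.66-fold. MIR155HG, the host transcript of microRNA miR-155, was not well above background in mock and was at least 3.66-fold higher in TRA2B4.

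Other genes that rose were FZD3, a receptor for Wnt ligands (at least 2.51-fold), GPRASP3 (at least 1.93-fold), ASAP1-IT1 (2.80-fold), the vault RNA VTRNA1-1 (at least 1.497-fold) and the dual-specificity phosphatase gene DUSP19 (at least 1.59-fold). The 10 genes that the naming rule picked among those that fell were well above background on the mock array and on neither TRA2B4 array, so each has a bound in place of a fold and their order is not known. The mock array alone was enough for them to enter the tests. ZDHHC15 and LVRN were each at least 10.5-fold lower, HHIPL2 at least 9.75-fold, C3P1 at least 7.87-fold and PKP1, a desmosomal plakophilin gene, at least 7.67-fold. INHBE, an inhibin subunit gene, was at least 7.02-fold lower, GRHL2, an epithelial transcription factor gene, at least 6.72-fold, ABCC13 at least 6.09-fold, OR7E5P at least 5.30-fold and PLXNA2, a semaphorin receptor gene, at least 5.27-fold. Adjusted p in limma was 0.0497 for HHIPL2 and 0.0476 for the other 19 of these genes. It tests the difference in signal, also where that was at background, and not the bound. Each of the 10 that fell had 1 probe past the filter, read on 1 mock array, so an artefact of single spots stays open for them. The other SEL1L probe past the filter gave 1.18 against 2.61 (log2), and the other H19 probe 1.41 against 1.54.

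Of the 26 gene lists fixed beforehand, 6 shifted in TRA2B4 against mock by camera with its preset correlation, and none did with an estimated correlation. That loss is not due to correlation alone, since the estimate for the list of splicing regulators was 0.007, below the preset 0.01. For cytosolic ribosomal protein genes it was 0.575 and for interferon-stimulated genes 0.564, far above the preset. In the amino acid and ER stress list, 23 members fell and 5 rose when adjusted over the list alone, and the 10 chaperone and degradation members had a median of 0.32. The list's median log2 fold change was -0.78, and CEBPB, a transcription factor gene of this response, fell by 1.56 ± 0.09. For the stress list the adjusted p was 3.05e-04, and 0.494 with an estimated correlation. In the immediate early and MAPK feedback list, 7 of 33 fell, 1 rose and 25 did not pass (median -0.59); adjusted over the list alone, 21 fell and 3 rose. DUSP1, a MAPK phosphatase gene, fell by 1.18 ± 0.09 and JUNB by 1.02 ± 0.09, while EREG, an EGF receptor ligand gene, rose by 0.95 ± 0.10. The list's adjusted p was 4.26e-04, and 0.494 with an estimated correlation. Among p53 target genes, 4 of 27 fell and 1 rose (median -0.36); adjusted over the list alone, 8 fell and 2 rose. GDF15, a stress cytokine gene, fell 6.48-fold, BBC3, a BH3-only death gene, 3.50-fold, GADD45A 2.39-fold and SESN2 4.66-fold, and TIGAR rose by 1.20 ± 0.11 (log2); SESN2 also belongs to the ER stress list. The p53 list had an adjusted p of 0.0451, and 0.767 with an estimated correlation. Its call ended without TRA2B4 replicate 2 (median -0.23, adjusted p = 0.0959), with median scaling (0.0929), with the mean of the probes of a gene (0.0825), with every probe on its own (0.120) and with fry (0.0656).

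Of 23 splicing regulators, a list of the SR and TRA2 families with hnRNP and CLK kinase genes, PTBP1 and ELAVL1, 16 lay above and 7 below mock in TRA2B4 cells, with a median of 0.25. The list's adjusted p was 7.49e-04, and 0.494 with an estimated correlation. SRSF1 rose by 1.25 ± 0.12 and SRSF8 by 0.89 ± 0.09, the same 2 members when adjusted over the list alone; SRSF4 was 0.45 ± 0.09 and SRSF6 0.43 ± 0.09 higher without passing. The other SRSF6 probe gave 0.01. Heat shock genes had a median of 0.23 with 0 of 20 members passing, over all genes or over the list alone; HSPA8 was 0.59 ± 0.09 higher, HSPA1B 0.79 ± 0.13, HSPA4 0.64 ± 0.14 and HSPA4L 0.76 ± 0.18. For this list the adjusted p was 0.0112, and 0.494 with an estimated correlation; with fry it was 0.0656. Cytosolic ribosomal protein genes had a median of -0.18 with 0 of 40 members passing by either adjustment (RPS14 -0.51 ± 0.09, RPS3 -0.56 ± 0.10, RPL11 -0.42 ± 0.09). Adjusted p for the list was 0.0300, and 0.767 with an estimated correlation. The ribosomal call ended with quantile scaling (median -0.05, adjusted p = 0.726, and -0.05 and 0.309 after normexp), without TRA2B4 replicate 1 (0.112), without either exon 2 array (0.0600), with the slide row (0.212) and with fry (0.118).

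**Figure D2:**
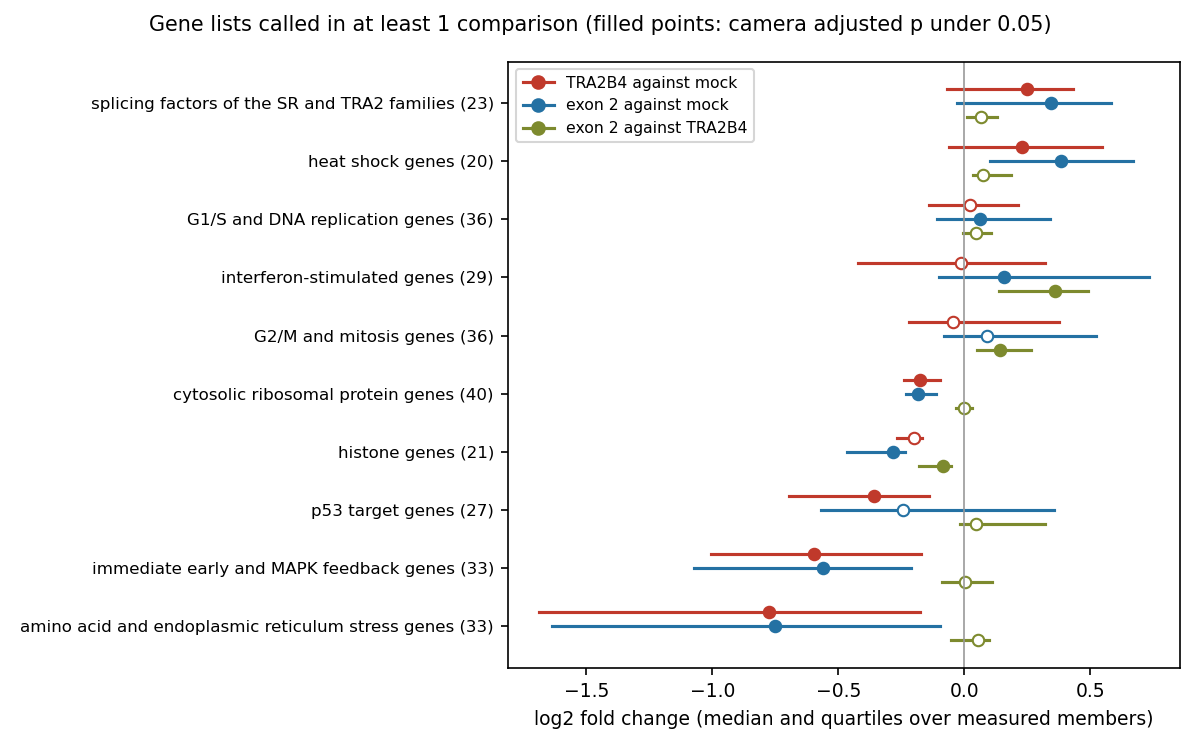
Median (points) and quartiles (lines) of the log2 fold change over measured members (horizontal axis) of the 10 gene lists called in at least 1 comparison (vertical axis, number of members in parentheses); filled points passed camera with its preset correlation. The amino acid and ER stress list had medians of -0.78 and -0.75 against mock and 0.05 between the constructs, and the interferon list had -0.01, 0.16 and 0.36.

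Over all genes, limma with Benjamini-Hochberg adjustment at 0.05 called 592 of 17861 features in TRA2B4 against mock, 171 higher and 421 lower, of which 414 differed at least 2-fold. All 592 had an adjusted p between 0.0476 and 0.05, and 5911 had an unadjusted p under 0.05. The split moved with the scaling, from 71.1% lower to 92.6% of 405 lower with median scaling, 53.7% of 2056 lower after normexp background correction, 55.7% of 1179 lower with probes well above background on all 5 arrays and 96.8% of 220 lower with the slide row as a covariate. Leaving out any 1 of the 4 overexpressing arrays left 0 calls in limma, with 3831 to 6677 features at an unadjusted p under 0.05, and the slide row as a covariate, chosen after seeing the data, left 220.

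The comparison of exon 2 with mock asked what exon 2 alone changes. The same stress genes were low in these cells: CHAC1 fell by 3.71 ± 0.10 (SE, log2; 13.1-fold; exon 2 n = 2, mock n = 1), CEBPB by 1.61 ± 0.09 and ASNS by 1.64 ± 0.09. SEL1L rose 6.40-fold, with 2.68 on the tested probe and 0.97 on the other. EGR1 fell 3.63-fold and JUN 4.35-fold. IFIT2, an interferon-induced gene, rose 2.64-fold, and SC5D, a sterol desaturase gene of cholesterol synthesis, rose 3.05-fold.

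Other genes that rose in exon 2 against mock were IL20RA, a cytokine receptor subunit gene (3.37-fold), FZD3 (at least 2.50-fold), DUSP19 (at least 1.75-fold), the inflammasome-family gene NLRP4 (at least 1.63-fold), SCAPER (at least 1.47-fold), CD300A and SLAIN2 (each at least 1.44-fold) and the integrin gene ITGB8 (at least 1.31-fold). The 10 genes picked by the rule among those that fell were again well above background in mock and on neither exon 2 array. Here too the mock array alone was enough for them to be tested. ZDHHC15 was at least 12.1-fold lower, HHIPL2 at least 11.2-fold, C3P1 at least 9.08-fold, PKP1 at least 8.84-fold, RLN3 at least 8.58-fold and INHBE at least 8.09-fold. GRHL2 was at least 7.75-fold lower, ABCC13 at least 7.03-fold, SEC16B at least 6.54-fold and PLXNA2 at least 6.08-fold. Adjusted p in limma lay between 0.0420 and 0.0499 for these 20 genes, and again tests the difference in signal, not the bound. Each of the 10 that fell had 1 probe past the filter here too.

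In exon 2 against mock, 8 of the 26 lists shifted by camera with its preset correlation, and none did with an estimated correlation. In the amino acid and ER stress list 15 of 33 members fell and 3 rose (median -0.75), or 23 and 4 adjusted over the list alone. In the immediate early and MAPK feedback list 12 of 33 fell and 2 rose (median -0.56), or 22 and 4 adjusted over the list alone; DUSP1 fell by 1.21 ± 0.09 and JUNB by 1.09 ± 0.09. In the list of splicing regulators 3 of 23 rose (median 0.34), or 9 adjusted over the list alone; SRSF1 rose by 1.19 ± 0.12, SRSF8 by 0.82 ± 0.09 and the hnRNP gene HNRNPA2B1 by 0.63 ± 0.09, and SRSF4 was 0.51 ± 0.09 higher without passing. Each of these 3 lists had an adjusted p of 1.96e-04, and of 0.404 with an estimated correlation. Among heat shock genes 2 of 20 rose (median 0.38), or 6 adjusted over the list alone; HSPA8, the constitutive HSP70, rose by 0.66 ± 0.09 and HSPA1B, an inducible HSP70, by 0.93 ± 0.13, while HSPA4L was 1.16 ± 0.18 and CHORDC1 0.51 ± 0.09 higher without passing. The test of this list gave an adjusted p of 0.00195, and 0.404 with an estimated correlation. The p53 list, called in TRA2B4, was not called in exon 2 (camera adjusted p = 0.190). Still, 7 of its 27 members fell and 2 rose (median -0.24), or 9 and 5 adjusted over the list alone.

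The other 4 lists called in exon 2 against mock were as follows. Interferon-stimulated genes had a median of 0.16, with 3 of 29 members that rose and 1 that fell, or 6 and 1 adjusted over the list alone; PARP9 rose by 0.92 ± 0.11 and HERC5 by 0.73 ± 0.11, and ISG20 fell by 0.85 ± 0.11. Camera gave the list an adjusted p of 0.0325, and 0.715 with an estimated correlation; without exon 2 replicate 1 the median was 0.03, adjusted p = 0.166. The interferon call also ended with probes well above background on all 5 arrays (0.0753) or at least 2 (0.0542), with the authors' values (0.0738), without either TRA2B4 array (0.0569) and with fry (0.373). G1/S and DNA replication genes had a median of 0.06 with 2 of 36 that rose, or 0 adjusted over the list alone; CLSPN, a checkpoint adaptor gene, rose by 1.00 ± 0.13 and POLA1, a DNA polymerase gene, by 0.80 ± 0.12, while CCNE2 was 0.89 ± 0.16 and MCM10 0.70 ± 0.13 higher without passing. For this list the adjusted p was 0.0261, and 0.470 with an estimated correlation; it was 0.0536 without either TRA2B4 array and 0.0507 without exon 2 replicate 2, and the median was 0.15 with quantile scaling. All 21 measured histone genes lay below mock (median -0.28), and 1 passed by either adjustment; not passing were H2AC20 at -0.55 ± 0.12, H4C2 at -0.32 ± 0.10 and H4C8 at -0.47 ± 0.14. Adjusted p for the list was 0.00465, and 0.624 with an estimated correlation; with fry it was 0.0735. All 40 cytosolic ribosomal protein genes lay below mock (median -0.18) with 0 passing by either adjustment (RPS14 -0.51 ± 0.09, RPS3 -0.45 ± 0.10, RPL11 -0.34 ± 0.09). The test of this list gave an adjusted p of 0.00576, and 0.715 with an estimated correlation. The call ended with quantile scaling (median -0.02, adjusted p = 0.606, and -0.04 and 0.481 after normexp), without exon 2 replicate 1 (0.166), with the slide row (0.0609) and with fry (0.118).

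**Figure D3:**
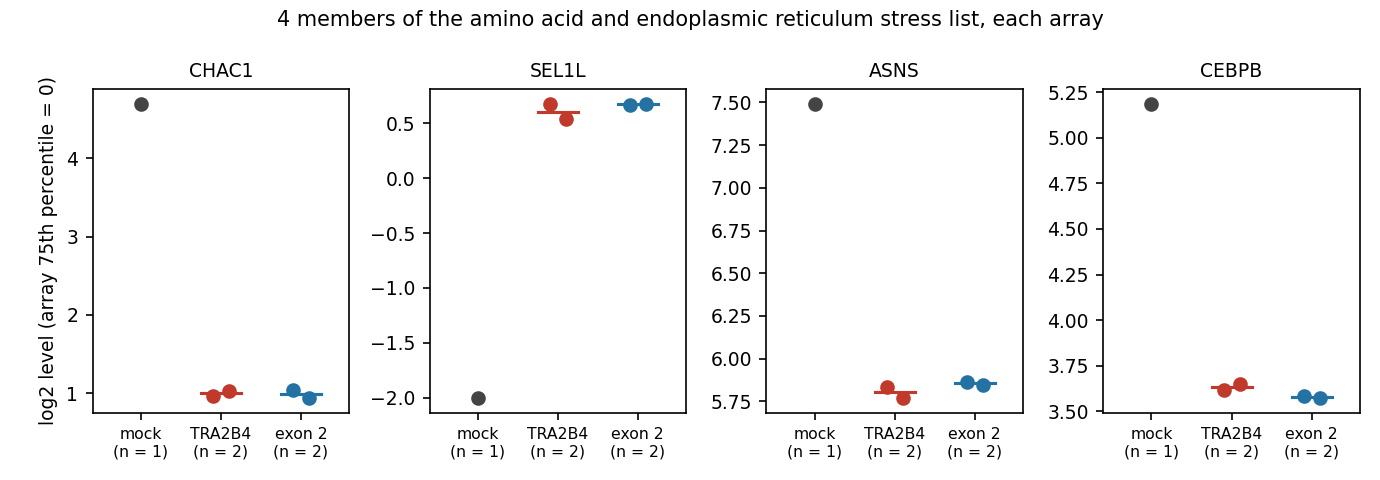
Log2 level (vertical axes, 0 at the array's 75th percentile, 1 scale per gene) of 4 members of the amino acid and ER stress list in mock, TRA2B4 and exon 2 cells (horizontal axis), with points for single arrays and lines for the means of groups with n = 2. CHAC1 lay at 4.70 in mock and between 0.94 and 1.04 on the other arrays, and SEL1L at -2.00 in mock and between 0.54 and 0.68 on the others.

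Over all genes, limma called 1306 of 17861 features in exon 2 against mock, 569 higher and 737 lower, of which 594 differed at least 2-fold. Their adjusted p lay between 0.0420 and 0.05, and 6141 features had an unadjusted p under 0.05. Which direction held the majority depended on the setting: 63 were higher and 326 lower with median scaling and 4 and 228 with the slide row, but 1519 and 1366 after normexp background correction, 1156 and 960 with probes well above background on all 5 arrays, and 1121 and 962 with the authors' values. The authors' values nearly repeat the setting with probes well above background on all 5 arrays. Leaving out any 1 of the 4 overexpressing arrays left 0 calls in limma, with 3320 to 7360 features at an unadjusted p under 0.05, and the slide row as a covariate left 232.

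The genes called in both overexpressing groups were compared to see whether the constructs changed the same genes. Among them were CHAC1, ASNS, CEBPB, EGR1, JUN and GDF15, which fell in both groups, and SEL1L, SRSF1, CDK6, TIGAR and EREG, which rose in both. In all, 155 features were called higher and 402 lower in both, 557 together, and 1 was called in opposite directions. Independent lists of these sizes would share 22.8 features, 5.45 higher and 17.4 lower, and 100 simulated datasets of unchanged groups against 1 shared control array gave a mean of 0.02 shared calls and at most 1. Such groups give few calls at all, and their spread came from the replicated arrays, so they do not represent a mock culture that deviates. Across genes, which are not independent replicates, the fold changes correlated at r = 0.906 against 0.668 in the simulated data, and their covariance was 0.411 against 0.0447. The 1 mock array stands in both comparisons and cannot be split, so part or all of the excess over chance may come from it. Leaving out any 1 of the 4 overexpressing arrays left 0 shared calls in limma.

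The comparison of exon 2 with TRA2B4 asked whether the constructs differ from each other, and it does not use the mock array for its fold changes. TRA2B4 replicate 1 differed less from exon 2 replicate 1 (SD 0.29) than from TRA2B4 replicate 2 (SD 0.43). MIR155HG had the smallest adjusted p of the named genes, 0.526, with a level of -1.37 ± 0.27 (SD, n = 2) in TRA2B4 and not well above background in either exon 2 array, at least 4.50-fold lower in exon 2. TRA2B probe A_33_P3297517 differed by -1.90 ± 0.18 (SE, log2) in exon 2, with an adjusted p of 0.788 over all probes. Probe A_23_P212639 differed by -0.24 ± 0.08, adjusted p = 0.788. CHAC1 (-0.01), ASNS (0.05), EGR1 (-0.14) and JUN (-0.17), low against mock in both groups, differed little here.

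In exon 2 against TRA2B4, 1034 of 17861 features had an unadjusted p under 0.05 in limma, little above the share of 0.05 that no difference would give. No feature passed after adjustment, the smallest adjusted p being 0.526. The genes picked by the naming rule are therefore given as not past the test. Lower in exon 2, without overlap between arrays, were KCNMB2 (at least 12.0-fold), SAXO1 (at least 4.02-fold), DPY19L2P2 (at least 3.13-fold), STMN2 (at least 3.02-fold), MIR221 (at least 2.38-fold), WDR17 (at least 2.24-fold), KRT32 (-3.33 ± 1.83, SE), RASA4B (-2.79 ± 1.70) and SFTPC (-2.27 ± 1.55). Higher in exon 2 were CDKN1A, the p21 cyclin-dependent kinase inhibitor gene (3.43 ± 2.09), JMJD1C (1.92 ± 1.21), KIAA1217 (1.41 ± 1.01), SOCS6 (1.38 ± 0.57), SLC12A8 (1.30 ± 0.73), ACADM (1.23 ± 0.81), IMPACT (1.21 ± 0.51), RAPGEFL1 (at least 4.06-fold), NTMT2 (at least 2.94-fold) and P2RX3 (at least 2.01-fold). Of these genes and MIR155HG, only MIR155HG had an SD under 0.80 in both groups. CDKN1A had an SD of 4.04 between the exon 2 arrays. For CDKN1A, KIAA1217 and SOCS6 only 1 of the 2 TRA2B4 arrays was well above background. The same held for KRT32 and SFTPC on the exon 2 arrays, so the differences of these genes are not exact.

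Of the 26 lists, 3 shifted between the constructs by camera with its preset correlation, with 0 members passing in any of them, over all genes or over the list alone. Interferon-stimulated genes were higher in exon 2 than in TRA2B4 for 28 of 29 members (median 0.36; PARP9 0.58 ± 0.09, HERC5 0.41 ± 0.09, IFIT5 0.29 ± 0.08, IFI6 0.51 ± 0.14). Camera gave the list an adjusted p of 5.90e-07, and 0.876 with an estimated correlation. G2/M and mitosis genes were higher for 29 of 36 (median 0.14; MAD2L1 0.27 ± 0.07, BUB1 0.26 ± 0.07, CDK1 0.26 ± 0.09, TTK 0.41 ± 0.14). For this list the adjusted p was 0.00395, and 0.876 with an estimated correlation. The mitosis call ended without exon 2 replicate 1 (adjusted p = 0.118), with quantile scaling (median 0.09, adjusted p = 0.0890) and with fry (0.388), and the median was 0.09 without TRA2B4 replicate 2 and 0.29 with median scaling. Histone genes were lower for 18 of 21 (median -0.08; H2BC21 -0.20 ± 0.07, H2AJ -0.48 ± 0.17, H4C8 -0.29 ± 0.12, with H1-4 at 0.36 ± 0.17). Adjusted p for the list was 0.00612, and 0.876 with an estimated correlation; the median was 0.06 with median scaling, which moved the median of all genes from 0.03 to 0.17 and so shifted all genes alike. The histone call ended without TRA2B4 replicate 2 (median -0.03, adjusted p = 0.725), without exon 2 replicate 1 (0.118), without a filter (0.274) and with fry (0.511). The interferon median was 0.21 without exon 2 replicate 1 (adjusted p = 0.0112) and 0.23 with normexp and the 75th percentile, and with fry the interferon call ended (0.426). The typical 95% interval of a single gene's log2 difference in this comparison reached 0.29 to either side.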

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

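The test of a deviating array was fixed before its result was seen, and the slide row values were chosen only after the data were seen. Interferon-stimulated genes differed between the constructs, with a median log2 difference of 0.36 (exon 2 less TRA2B4) in a direct comparison by camera with its preset correlation, a call that was lost with an estimated correlation (adjusted p = 0.876). The difference was 0.47 within slide row 1 and 0.23 within row 2, and the slide row as a covariate left it past the threshold. A single deviating array may account for part of it: leaving out exon 2 replicate 1 lowered the median to 0.21, between the bounds set for and against this explanation, and leaving out each of the other 3 overexpressing arrays left 0.33 to 0.47. Relative to mock, exon 2 replicate 1 lay 0.33 higher and exon 2 replicate 2 0.03 higher, and TRA2B4 replicates 1 and 2 lay at -0.13 and 0.03. A difference between the constructs, 1 deviating exon 2 culture and the slide column, which went with the group, cannot be told apart with 2 arrays per group.

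G2/M and mitosis genes also differed between the constructs in that comparison, with a median of 0.14 higher in exon 2, and histone genes with a median of -0.085; with an estimated correlation neither passed (adjusted p = 0.876 for each). Within slide rows 1 and 2 the mitosis genes differed by 0.11 and 0.15 and the histone genes by 0.00 and -0.20.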

How the results depend on the processing

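The slide row covariate was chosen after seeing the data. The other alternatives were fixed before. The authors' values and the filter for probes well above background on all 5 arrays gave nearly the same data (15700 and 15712 features). These settings are therefore not separate checks. For TRA2B4 against mock, exon 2 against mock and genes called in both, counts were 592, 1306 and 557. They became 2056, 2885 and 1841 with normexp and the 75th percentile, 2263, 2932 and 1982 with normexp and quantile scaling, 1179, 2116 and 1085 with probes well above background on all 5 arrays, 1152, 2083 and 1058 with the authors' values, 3423, 4092 and 2871 with a trended, robust variance model, and 220, 232 and 209 with the slide row. Median scaling gave 389 for exon 2 and 330 shared, quantile scaling 616 and the 2-fold minimum 594 for exon 2. In limma all 3 counts were 0 without a filter (3468 and 3856 features at an unadjusted p under 0.05 in TRA2B4 and exon 2), with a filter of at least 2 arrays (5528 and 5735), and with only the arrays of the 2 groups (3831 and 7360). Testing every probe on its own gave 0 for TRA2B4 (7266 at an unadjusted p under 0.05) and for shared calls, and 1229 for exon 2. Leaving out 1 array gave 0 in every case for these counts. Leaving out either array of the group not compared gave the same fit as using only the arrays of the 2 groups, so these settings are not separate. The main calls lay just under the threshold, with 2 residual degrees of freedom. These fell to 1 when an array was left out, the lone sample then being assumed to vary like the other groups. The cause of the other moves was not tested. Exon 2 against TRA2B4 gave 0 calls in limma under every alternative, with 501 to 2614 features at an unadjusted p under 0.05.

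Gene lists called were 6, 8 and 3 in the order TRA2B4 and exon 2 against mock and exon 2 against TRA2B4. With an estimated correlation they were 0, 0 and 0, and with fry, which called partly different lists, 6, 9 and 0. Without a filter there were 10 in TRA2B4 against mock and 7 between the constructs. Leaving out 1 array gave 5 to 6, 6 to 8 and 1 to 4. The median of histone genes between the constructs was 0.058 (adjusted p = 0.0445) with median scaling against -0.085, and the all-gene median moved from 0.03 to 0.17: that scaling moves all genes alike, so the list's shift relative to all genes did not reverse. No other list or named-gene result changed label to reversed. The replicate number of the overexpressing arrays is also their slide row, so the replicate block and the slide row give the same fit between the constructs. The labels name no pairing, and the difference of replicate 1 less 2 in TRA2B4 correlated with that in exon 2 at 0.07 across genes. With the replicate block on the 4 overexpressing arrays, exon 2 against TRA2B4 had 0 calls in limma (865 features at an unadjusted p under 0.05) and 3 lists. The slide as a block was not run, since all arrays lay on 1 slide, and the fold minimum does not apply to lists. Between 42.9% and 45.8% of the probes were well above background on each array, and where 1 group is at background only bounds on its fold are known.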

Other observations

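Of the explanations weighed here, an effect of the constructs, the slide column and artefacts of single spots were put to a test only after their results were seen. The other 16 gene lists were called by camera in none of the comparisons, yet single members changed against mock. With fry, apoptosis regulators passed in TRA2B4 (adjusted p = 6.49e-04) and exon 2 (0.00221) against mock. Mesenchymal genes and epithelial adhesion and keratin genes also passed with fry in both, and cholesterol synthesis genes in exon 2. CDK6 rose 2.54-fold and the retinoblastoma gene RB1 1.89-fold in exon 2, after 2.66-fold and 1.77-fold in TRA2B4 (cell cycle inhibitors and senescence regulators, list adjusted p = 0.190 and 0.330), and in exon 2 CDKN2D fell 1.61-fold. Of the secretory genes of senescent cells, VEGFA fell 2.06-fold and EREG rose 1.93-fold in TRA2B4, and VEGFA fell 2.24-fold, EREG rose 2.01-fold, IGFBP7 rose 1.64-fold and the urokinase gene PLAU fell 1.66-fold in exon 2. The pioneer factor gene SOX9, of the Wnt and intestinal stem cell list, fell 1.79-fold in TRA2B4 and 1.69-fold in exon 2, the order of the values that follow. In epithelial adhesion and keratin genes, KRT80 fell by 1.20 and 1.27 (log2) and KRT7 by 1.73-fold and 1.80-fold, while the desmosomal cadherin gene DSG2 rose 1.85-fold and 2.01-fold. The death gene HRK, of the apoptosis regulators, fell 2.27-fold in each group, and the NRF2 target AKR1B10 fell 2.26-fold and 2.44-fold.

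Passing in exon 2 against mock were also SNAI2, a mesenchymal transcription factor gene, which fell 4.79-fold, beside ITGAV, which rose 1.94-fold, and AXL, which fell 1.53-fold, the intestinal differentiation gene KLF4, which fell 1.89-fold, the cholesterol synthesis gene SC5D, which rose 3.05-fold, and TM7SF2, which fell 1.57-fold (3 rose and 1 fell in that list), the nucleolar genes DDX21 and NCL, which rose 1.84-fold and 1.70-fold, the decay genes DCP2 and XRN1, which rose 1.93-fold and 1.87-fold, with SMG5, which fell 1.60-fold, and the integrin gene ITGB1, which rose 1.63-fold. Of NF-kB target genes 4 of 18 fell, among them NFKB2 by 1.63-fold, and of hypoxia and glycolysis genes VEGFA and EGLN3 fell in both groups. No member of the metallothionein or oxidative phosphorylation lists passed in any comparison, in limma; their medians were 0.03 and -0.15 in TRA2B4 and -0.08 and -0.11 in exon 2. Markers of other cell types were mostly dim: 2 of 10 fibroblast, 6 of 12 immune, 3 of 8 endothelial, 2 of 8 neuroendocrine, 2 of 8 hepatocyte and 4 of 8 neural or HEK293-type markers were tested. CD68 passed against mock, with a log2 fold change of -0.81 ± 0.10 in TRA2B4 and of -0.71 in exon 2. In exon 2, PDGFRB at -0.90 ± 0.10 and ESAM at -0.73 ± 0.10 (log2) also passed.

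The amino acid and ER stress list had a median below mock in both overexpressing groups (-0.78 in TRA2B4 and -0.75 in exon 2). Scaling or background correction would need a list shift near that of all genes, but the list's median less that of all genes came no closer to 0 than -0.58 over the 75th percentile, quantile and both normexp settings and both comparisons. The row of the slide would need a small difference within slide row 2, where the median was -0.72 for exon 2 and -0.79 for TRA2B4. General ER stress of the mock culture would lower the chaperone and degradation members with the rest, but their median over 10 members was 0.32 in TRA2B4 and 0.30 in exon 2 (HSPA5 0.75 and 0.85, HERPUD1 -0.64 and -0.66), against -1.42 and -1.38 for the other 23. An effect of the constructs and the slide column cannot be told apart, because 0 overexpressing arrays shared a column with the mock array, and an amino acid stress of the mock culture alone stays open with 1 mock array.

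More genes were called lower than higher in TRA2B4 against mock (71.1% of 592 lower). Genomic DNA in the mock sample would raise olfactory receptor genes there; their 378 probes were higher in mock by a median of 0.13, and the 28032 probes left out as dim by 0.14. With probes well above background on all 5 arrays 55.7% of 1179 calls were lower, but calls rose in both directions (657 lower and 522 higher, from 421 and 171). That filter removes genes at background in 1 group, so a part for dim probes stays open. The main filter itself favoured lower calls. A probe bright on the mock array alone was tested, while one bright on 1 overexpressing array alone was not. Artefacts of single spots were tested for the 37 genes called lower with another probe past the filter. Their 49 other probes had a median of -0.91, 46 of them below 0. Those probes had passed the same filter, which favours values below 0, and how many entered through the mock array alone was not counted. The values therefore argue against such artefacts only in part. For the 384 genes called lower without such a probe no value decides, so single spots stay open there.

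By processed signal, also where it was at background, the mock array stood above each of the other arrays by a factor of 8 at 112 of 17861 features. As 107 of these were well above background on the mock array alone, the factor is no bound on their fold. TRA2B4 replicate 2 stood out in this way at 16 features, exon 2 replicate 2 at 4, and TRA2B4 replicate 1 and exon 2 replicate 1 at 1 each. These counts cannot be compared with that of mock. The filter let in probes bright on the mock array alone, but none bright on 1 overexpressing array alone. Of the features counted for each overexpressing array, 0 were well above background on that array only. The mock array lay below all others by that factor at 1 feature. CDKN1A, the p21 gene, was at 3.16 (log2) on exon 2 replicate 2 and between -3.24 and -1.31 on the other 4 arrays.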
